A study of Mus musculus with 5 samples.

How the data were processed

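Gene expression was measured on Illumina expression arrays in F9 cells, a mouse embryonal carcinoma line that differentiates towards extra-embryonic endoderm when treated with retinoic acid. Every sample carried the same retinoic acid label, whose dose and duration the labels do not give. The samples formed 2 groups: 2 control arrays and 3 arrays of cells in which Sox7 and Sox17 were knocked down together. How the knockdown was made, and what the control cells received, is not given in the sources used here. Total RNA was extracted with Trizol, cleaned on RNeasy columns with DNase I treatment, and turned into biotinylated cRNA with the Ambion MessageAmp kit, per the labels' protocols. Nothing in the labels says that the numbered samples came from separate cultures. The p-values of single genes therefore measure the spread between these samples, which may be technical.

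The values analysed were the deposited normalized intensities, 1 per probe and sample, for 24613 probes. They were on a linear scale with a minimum of -37.5 and a maximum of 49024. Between 29.1% and 29.2% of the values of each array lay below 0, so background had been subtracted before deposit. The sorted values of the 5 arrays differed by at most 0.394, so the arrays had also been brought to 1 common distribution. The software and the method of both steps are not given in the sources used here. This normalization removes any overall difference in RNA amount between arrays. A second deposited table, of non-normalized signals and detection p-values, was not used, because its 10 per-sample columns have headings that match no sample's labels. The plan made before the data were examined, background correction and quantile normalization of scanner signals with a filter on detection p-values, was therefore replaced by its fallback, a test on the log2 scale of the normalized table. The offset was kept from the plan, and the noise threshold described next, which stands in for detection p-values, was chosen after seeing the data.

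Intensities below 0 were set to 0, an offset of 16 was added, and the base-2 logarithm was taken. All differences below are knockdown minus control on this log2(intensity + 16) scale, which understates changes of dim probes. The noise level of each array was estimated from its own values below 0, mirrored around 0. The one-sided 0.05 noise threshold, the 90% quantile of their sizes, lay between 20.1 and 20.2 intensity units. Between 12953 and 12968 probes per array (52.6% to 52.7%) were above it. The precision is limited by the number of arrays. Probes above the threshold on at least 2 of the 5 arrays, whatever their group, were tested, which left 13624 probes. A probe under the threshold on every array of a group has only a bound there, and its change is given as "at least" a fold. That bound is the mean log2 intensity of the brighter group minus the mean of the higher of threshold and own signal in the dimmer one.

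Gene names came from the platform's probe annotation, with symbols checked through the gene identifier against the mouse RefSeq annotation of GRCm38.p6. No symbol needed updating, and 16 had no match and were kept. Of the probes, 20984 had 1 gene symbol, 1 had several and 3628 were not listed and stay unnamed. A gene was represented by its tested probe with the highest mean over all 5 arrays, giving 9685 genes. Probe sequences were not used, and paralogs can share a probe's signal.

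Each probe was tested with limma 3.58.1 in R 4.3.3 (tables and figures were made in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9) (lmFit and eBayes, 3 residual degrees of freedom), double knockdown against control over all 5 arrays with no covariate. P-values were adjusted by Benjamini-Hochberg over the tested probes, and a call needs an adjusted p below 0.05. Every adjusted p for a gene comes from this fit. A permutation of single values cannot pass that threshold here, because 5 arrays split into 2 and 3 in 10 ways and the smallest p is 0.1. The fit was tested on simulated data with the real probe means and spreads. Of 13624 probes, 200 were changed, with 50 at each fold. The fit recovered 20% of probes changed by 1.5-fold, 84% at 2-fold and 100% at 4-fold and at 8-fold. It also called 13 unchanged probes, and called 0 when no probe was changed. The real data had more called probes, 2165 of 13624, and a share of changed probes like that was not simulated.

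A total of 28 gene lists were fixed before the data were examined, without the targeted genes. They cover endoderm, matrix, pluripotency, retinoic acid and signalling genes, and markers of other cell types that a culture could hold. Each was tested with limma's camera (inter-gene correlation 0.01, two-sided, Benjamini-Hochberg over the lists). At this preset correlation camera compares the members with all other genes. Its p-values then rest mainly on the spread between genes, which are treated as nearly independent, and not on replication between samples. In an alternative the correlation was estimated from the data. Camera then takes its p-values from the 3 residual degrees of freedom, so a higher p there need not reflect a stronger correlation. The number of called members is given after adjustment over all tested probes and also adjusted over the list alone. The genes named were chosen by a rule fixed beforehand. It takes Sox7 and Sox17, the 12 largest falls and 12 largest rises among called genes whose knockdown values all lay on 1 side of both control values (placeholder symbols left out), and for each list up to 4 members with the smallest adjusted p. The text gives fewer of the last kind where a list has many. Alternatives covered the offset, a floor, the filter, the variance model, the replicate number as a block, each array left out, the call threshold, the rule for several probes and the set test.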

Results

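The data comprised 5 arrays of retinoic acid-treated F9 cells, 2 of control cells and 3 of cells with Sox7 and Sox17 knocked down together. The design asked which transcripts depend on this pair of related transcription factors, which act in endoderm and endothelial development. Arrays of a group resembled each other more than arrays of different groups. Pearson's correlation of log2 values was 0.993 between the control arrays and 0.992 between each pair of knockdown arrays, against 0.974 to 0.978 between groups. The first principal component held 66.5% of the variance and placed the control arrays at -31.0 and -33.3 and the knockdown arrays at 19.6 or above. No 2 arrays held identical values.

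Both targeted transcripts were lower in every knockdown array. The Sox17 probe (ILMN_2747986) had an intensity of 1765 ± 46.3 (SD, n = 2) in control cells and 278 ± 33.1 (SD, n = 3) in knockdown cells, a fall by 2.60 on the log2 scale (SE 0.125, limma adjusted p = 0.00081). The Sox7 probe (ILMN_2653251) had 1229 ± 109 in control cells and 455 ± 45.7 in knockdown cells, and fell by 1.40 (SE 0.126, adjusted p = 0.0021). On this scale knockdown cells kept 16.5% of the control level of Sox17 and 37.8% of that of Sox7. Both calls held with each array left out in turn, with adjusted p at most 0.014 for Sox17 and 0.023 for Sox7.

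**Figure D1:**
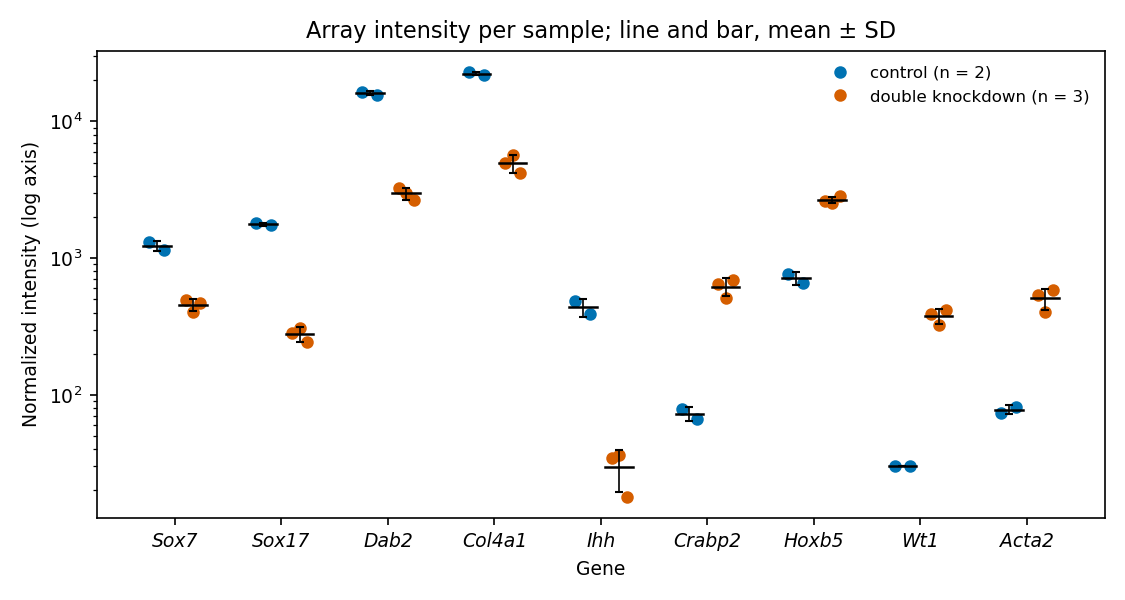
Normalized intensity (log axis) of 9 genes in each of the 2 control and 3 double-knockdown arrays; points are arrays, lines and bars the mean ± SD. Sox7, Sox17, Dab2, Col4a1 and Ihh were lower and Crabp2, Hoxb5, Wt1 and Acta2 higher in all 3 knockdown arrays than in both control arrays.

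Many genes changed in each direction. Among them the endocytic adaptor gene Dab2, the collagen gene Col4a1 and the hedgehog ligand gene Ihh fell, and the retinoic acid-binding protein gene Crabp2, the homeobox gene Hoxb5 and the transcription factor gene Wt1 rose. Of 9685 genes tested, 1643 were called, 871 higher and 772 lower. At least 1.5-fold, 547 were higher and 543 lower, and at least 4-fold, 19 were higher and 45 lower. The corresponding count over 13624 probes was 2165, with 1142 higher and 1023 lower, and the median difference over all tested probes was 0.0050. The groups did not overlap for 51.6% of the genes, where chance gives 20%. Leaving out an array lowers the residual degrees of freedom, so a call lost this way need not mean a changed difference. The number of called genes fell whichever array was left out. It was 578 without control replicate 1, 443 without control replicate 2, 1034 without knockdown replicate 2 and 883 without knockdown replicate 3, against 1108 without knockdown replicate 1.

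**Figure D2:**
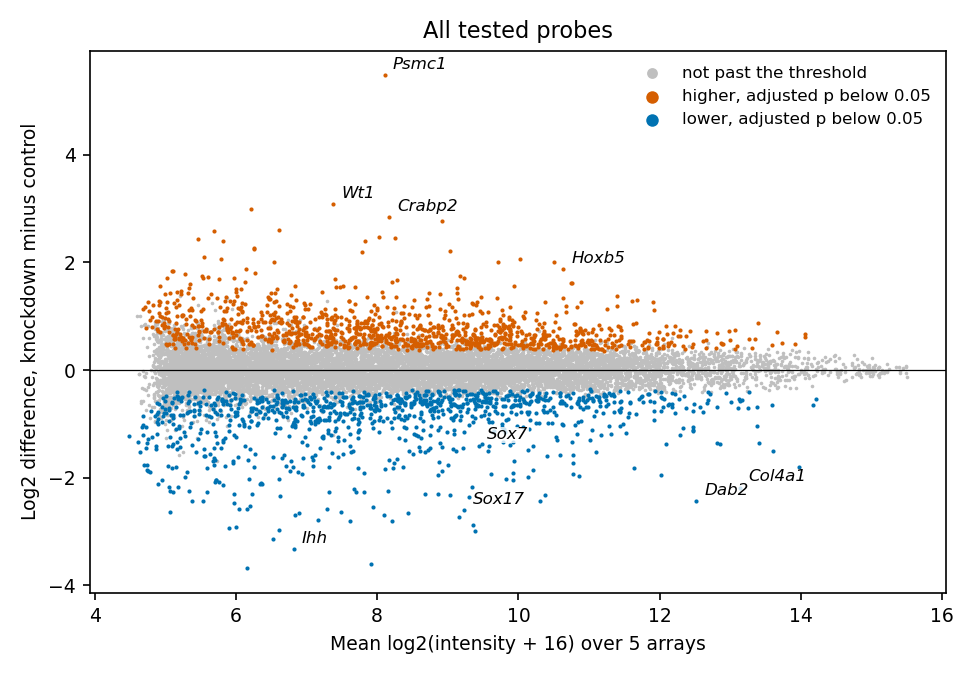
Log2 difference (knockdown minus control) against mean log2(intensity + 16) for the 13624 tested probes; colours mark the 1142 higher and 1023 lower probes with adjusted p below 0.05. Falls outnumber rises among the genes called at 4-fold or more (45 against 19), and the Psmc1 probe stands above all others.

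The 12 largest falls were in genes of varied function. Ugt2b34, a UDP-glucuronosyltransferase gene, went from 315 ± 18.4 (SD, n = 2) to below the noise threshold in all knockdown arrays, at least 15.6-fold lower (adjusted p = 0.00081). Its paralogs can share the probe's signal. Habp2, a secreted serine protease, fell by 3.61 (SE 0.265), from 1069 to 75.9 intensity units, and its other tested probe fell by 2.18. Ihh, a hedgehog ligand of visceral endoderm, fell by 3.33 (SE 0.216), and the transcriptional coactivator Cited1 fell by 3.14 (SE 0.315). Ttr, the thyroid hormone carrier transthyretin, was at least 9.27-fold lower. Klb, a co-receptor for endocrine FGFs, fell by 2.87 (SE 0.195), from 2146 to 284. The potassium channel gene Kcnk13 fell by 2.81 and Bmper, a secreted BMP-binding protein, fell by 2.81 as well. P3h2, a collagen prolyl hydroxylase, fell by 2.78, Hs3st1, a heparan sulfate sulfotransferase, fell by 2.74, the scaffold gene Pdzd3 fell by 2.70 and the pepsinogen gene Pga5 fell by 2.69. All 12 had adjusted p of at most 0.0030 and kept their call with each array left out.

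The 12 largest rises were also in genes of varied function. The probe for Psmc1, an ATPase subunit of the proteasome, was under the noise threshold in both control arrays (12.5 ± 4.74, SD, n = 2) and at 1248 ± 182 (n = 3) in knockdown cells, at least 61.4-fold higher (adjusted p = 0.00052). Wt1, a transcription factor of the urogenital mesoderm, rose by 3.09 (SE 0.132), from 30.1 to 378 intensity units. Cyp1b1, a monooxygenase, was at least 7.65-fold higher, and the growth factor Ptn at least 9.15-fold higher. Crabp2, a cellular retinoic acid-binding protein, rose by 2.83 (SE 0.155), from 72.5 to 619. Csn3, kappa-casein, rose by 2.76, Acta2, smooth muscle actin, by 2.46 and Nnat, an imprinted gene, by 2.46, with 2.59 at its other probe. Meox1, a homeobox gene of somites, rose by 2.40, and Crispld2 was at least 3.50-fold higher. Sspn rose by 2.26 (SE 0.483, adjusted p = 0.029) and Avil by 2.26 (SE 0.515, adjusted p = 0.036), with control replicate 1 below 0 for both and control replicate 2 at 39.6 and 40.1 intensity units. The call of Sspn was lost without any 1 of the knockdown arrays and that of Avil without any 1 array other than control replicate 2, with adjusted p up to 0.081 and 0.097.

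Many regulators and markers of extra-embryonic endoderm fell. Of 14 tested regulators of primitive endoderm, 12 fell and 0 rose. Dab2, an endocytic adaptor needed for endoderm organisation, fell by 2.44 (SE 0.117), from 16120 ± 554 to 2970 ± 290 intensity units. The receptor gene Pdgfra fell by 1.97 (SE 0.130), the transcription factor gene Hnf4a fell by 1.54 (SE 0.103) and Foxq1 fell by 1.38 (SE 0.105). Of the members named after their values were seen, the endoderm transcription factor genes Gata4 and Foxa2 fell by 1.40 and fell by 1.79. Fgfr2 also fell, and a dimmer probe of it differed by 0.27 and was not called. Of 16 tested genes of visceral endoderm, 11 fell and 1 rose. Amn, an endocytic receptor subunit, fell by 1.85 (SE 0.107), beside Ttr, Ihh and Hnf4a. The exception, named after its value was seen, was the transferrin gene Trf, which rose by 1.01 and lost its call without control replicate 1, knockdown replicate 2 or knockdown replicate 3 (adjusted p = 0.067, 0.051 and 0.051). Of the 24 visceral endoderm genes with a probe, only these 16 were tested. Afp, Apoa4, Apob, Cer1, Fgb, Fgg, Tdo2 and Slc2a2 had probes that did not pass the filter on dim probes. Of 20 tested genes of parietal endoderm, 16 fell and 0 rose, with a median of -1.43. Adjusted over the list alone, 12 fell and 1 rose, 11 fell and 1 rose, and 17 fell in the 3 lists. The lists' camera adjusted p-values were 3.9e-09, 2.7e-06 and 7.6e-12, in the same order. With an estimated correlation none passed, at adjusted p = 0.11, adjusted p = 0.18 and adjusted p = 0.12. Without control replicate 2, 9, 8 and 11 members fell, and without control replicate 1, 9, 7 and 12.

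Genes that build and process the basement membrane fell in part, and some of its genes rose. Col4a1 and Col4a2, the type IV collagen chains, fell by 2.18 (SE 0.144) and fell by 1.81 (SE 0.100), from 22402 to 4949 and from 33985 to 9719 intensity units. Lamb1, a laminin chain, fell by 1.95 (SE 0.111) and Sparc, a collagen-binding matrix protein, fell by 1.81 (SE 0.117). Of 19 tested basement membrane genes, 7 fell, 3 rose and 9 were not called (7 and 3 adjusted over the list alone). All of those that fell except Hspg2, named after its value was seen, are also on the parietal endoderm list. The falls in the 2 lists are therefore largely the same genes and not separate findings. The genes that rose, named after their values were seen, were Col18a1 by 1.28, Smoc2 by 1.09 and Lama5 by 0.84. Without control replicate 2, 6 fell and 1 rose. The call of Smoc2 was lost without control replicate 1 or control replicate 2 (adjusted p = 0.054 and 0.087), and that of Lama5 without any single array other than control replicate 1 (adjusted p from 0.052 to 0.090). Of 17 tested genes of collagen folding and secretion, 12 fell and 0 rose (13 and 0 adjusted over the list alone), led by P3h2 and by P4ha2, a collagen prolyl hydroxylase subunit that fell by 1.72 (SE 0.112). The lysyl hydroxylase gene Plod3 fell by 1.13 (SE 0.101). Without control replicate 1 the number was 5, and without control replicate 2 it was 5 as well. Camera gave adjusted p = 0.0096 for the basement membrane list and 3.7e-08 for collagen folding. With an estimated correlation these became adjusted p = 0.36 and adjusted p = 0.11.

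Genes of endocytosis and the lysosome also fell, with 10 of 18 tested members lower and 0 higher. Beside Dab2 and Amn, the cysteine protease genes Lgmn and Ctsh fell by 1.37 (SE 0.0979) and fell by 1.88 (SE 0.161), Lgmn from 19191 to 7448 intensity units. Adjusted over the list alone, 10 fell and 1 rose, and without control replicate 1 or control replicate 2 the number was 6. Of 18 genes of the unfolded protein response, 3 fell and 0 rose (3 and 0 adjusted over the list alone). Ddit3, a stress-induced transcription factor gene, fell by 1.98 (SE 0.191), Atf3 fell by 1.03 and Trib3 fell by 0.39. The call of Trib3 was lost without any single array (adjusted p from 0.088 to 0.20). That of Atf3 was lost as well without control replicate 1, control replicate 2 or knockdown replicate 1 (adjusted p up to 0.11), which left 1 of the 3 falls there and 2 without either other array. Hsp90b1, an endoplasmic reticulum chaperone, differed by -0.37 (adjusted p = 0.093). Camera gave adjusted p = 6.0e-06 and 0.0069 for these lists. With an estimated correlation the values were adjusted p = 0.12 and adjusted p = 0.24.

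**Figure D3:**
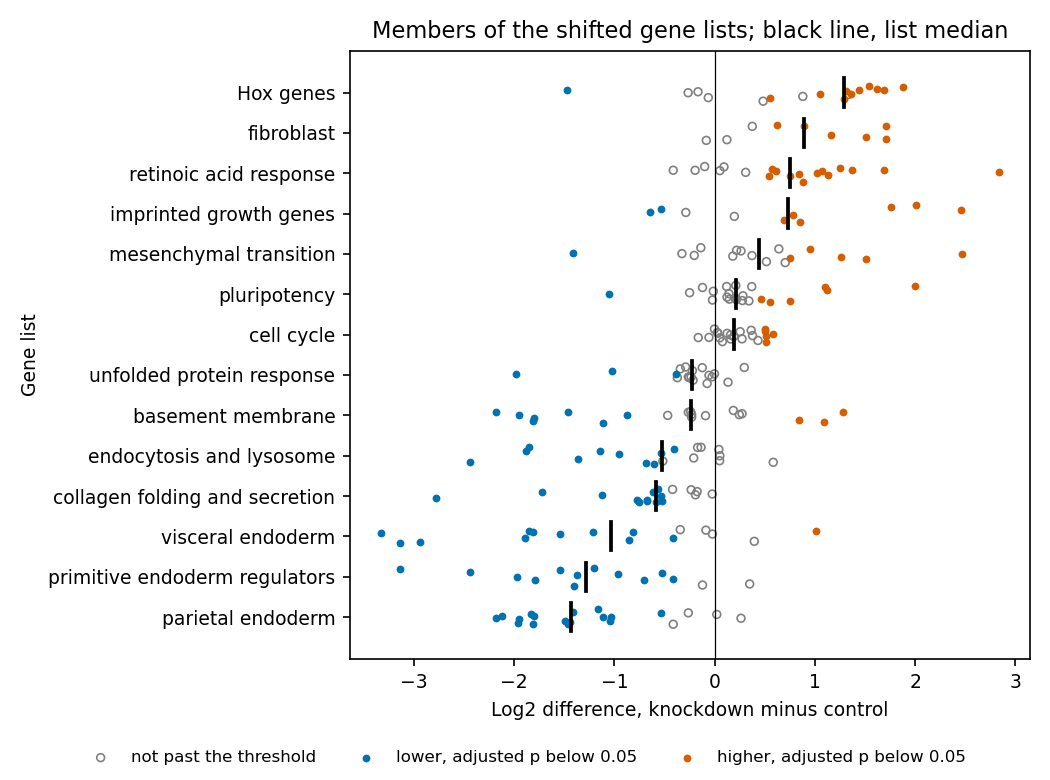
Log2 difference (knockdown minus control) of each tested member of the 14 lists shifted by camera at its preset correlation; filled points passed the threshold (blue lower, orange higher), open points did not, and black lines are list medians. Medians run from -1.43 for parietal endoderm to 1.29 for Hox genes.

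Many retinoic acid response genes and Hox genes rose. Of 19 tested retinoic acid response genes, 13 rose and 0 fell, with a median of 0.75. Among those that rose, Hoxb1 is also on the Hox list and Dusp6 on the FGF and ERK list. Cdx1 is also on the Wnt target list and Stra8 on the germ cell list, so these rises are not separate findings there. Beside Crabp2, the homeobox genes Hoxb1 and Meis2 rose by 1.69 (SE 0.128) and 1.25 (SE 0.114), and Tgm2, a transglutaminase, rose by 0.84 (SE 0.0949). Not every known target moved. Rarb and Cyp26a1, named after their values were seen, differed by -0.19 and -0.10 and were not called. Of 17 tested genes on the Hox list, 10 rose and 1 fell. The list holds only part of the Hox genes measured: over all 22 tested, a count made after the values were seen, 10 rose and 3 fell. Hoxb5 rose by 1.88 (SE 0.115), from 716 ± 78.3 to 2666 ± 155 intensity units, Hoxb2 by 1.62 (SE 0.128) and Hoxa4 by 1.44 (SE 0.0995). Hoxd8, named after its value was seen, fell by 1.48. Adjusted over the list alone, 13 rose and 1 fell in each list. Camera adjusted p-values were 2.7e-06 for the retinoic acid list and 5.6e-06 for Hox genes, and with an estimated correlation both had adjusted p = 0.12. Without control replicate 2, 7 of the retinoic acid genes and 9 of the Hox genes rose.

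Several mesenchymal and fibroblast marker genes rose. Of 16 genes of mesenchymal transition, 5 rose and 1 fell. Acta2, the transcription factor gene Twist2 (by 1.51, SE 0.111), and Mmp2, a matrix metalloproteinase (by 1.26, SE 0.0955), rose. Snai1, a gene also on the parietal endoderm list and named after its value was seen, fell by 1.42, a call lost without control replicate 1 (adjusted p = 0.097) or control replicate 2 (adjusted p = 0.11). Of 9 tested fibroblast markers, 6 rose and 0 fell, among them Loxl1, a lysyl oxidase relative, by 1.70 (SE 0.102). Mfap5, a microfibril protein gene, rose by 1.16 (SE 0.162). The fibroblast collagen genes Col1a1, Col1a2 and Col3a1 were not tested, since no probe of theirs passed the filter. Adjusted over the list alone, 9 rose and 2 fell in the first list and 7 rose in the second. Camera gave adjusted p = 0.0025 and 0.00011, against adjusted p = 0.13 and adjusted p = 0.12 with an estimated correlation. Without control replicate 2, 4 genes of each list rose.

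Some pluripotency, cell cycle and imprinted genes changed. Of 22 tested genes, 6 rose, 1 fell and 15 were not called (7 and 1 adjusted over the list alone), with a median of 0.21. Lefty2, a Nodal antagonist, rose by 2.00 (SE 0.152), from 618 to 2509 intensity units. Lefty1 differed by 1.12 (adjusted p = 0.010) and Lin28a, an RNA-binding protein gene, by -1.05 (adjusted p = 0.0083). The call of Lefty1 was lost without control replicate 2 and that of Lin28a without control replicate 1, at adjusted p of 0.056 and 0.059. Of the core factors, named after their values were seen, Nanog rose by 0.46 (adjusted p = 0.039), a call lost without any single array (adjusted p from 0.058 to 0.19), and Pou5f1, Sox2 and Esrrb differed by 0.22, 0.37 and 0.15 and were not called. Without control replicate 1, 2 members rose and 0 fell, and without control replicate 2, 1 rose and 1 fell. Of 21 cell cycle genes, 5 rose and 0 fell (8 and 0 adjusted over the list alone), with values from 0.50 to 0.58, among them the replication genes Pcna, Ccne1, Mcm5 and Mcm6. Of the other Mcm6 probes, 1 rose by 0.93 and 1 differed by 0.012 and was not called. Without control replicate 1, control replicate 2 or knockdown replicate 1, 0 of the list's genes were called, and without knockdown replicate 2 or 3 the number was 1. Of 10 imprinted growth genes, 6 rose and 2 fell (6 and 3 adjusted over the list alone), among the former Mest by 2.01 (SE 0.116), Dlk1 by 1.76 (SE 0.0948) and Nnat. A dimmer Mest probe differed by 0.83 and was not called. Without control replicate 1, and also without control replicate 2, 3 rose and 0 fell. Without knockdown replicate 1 or 3, 5 rose and 0 fell, and without knockdown replicate 2, 6 rose and 1 fell. Camera adjusted p-values were 0.0039, 0.0045 and 0.016 for these lists. With an estimated correlation they were adjusted p = 0.19, adjusted p = 0.13 and adjusted p = 0.24.

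The other 14 lists did not pass as groups, although single members did. Their members gave 35 rises and 21 falls in all, against 17 and 9 without control replicate 1, 13 and 8 without control replicate 2, 28 and 20 without knockdown replicate 1, 20 and 16 without knockdown replicate 2, and 16 and 16 without knockdown replicate 3. Of the 44 called genes that the naming rule gave for these lists, only 18 kept their calls with each array left out in turn, and the members printed below are mostly of these 18. Among markers of other cell types, the neuroectoderm list had 4 higher and 1 lower of 10 (5 and 1 adjusted over the list alone; adjusted p = 0.085), with Gap43, a growth cone protein gene, and Pou3f1 higher by 1.23 and 1.54. The neurofilament gene Nefm was at least 1.53-fold lower, a call lost without control replicate 1 or control replicate 2 (adjusted p up to 0.11). The trophoblast list had 3 lower and 0 higher of 11 (3 and 0 over the list alone; adjusted p = 0.061), and Plac1 fell by 1.19. Primitive streak genes had 1 higher and 1 lower of 8 (1 and 1 over the list alone; adjusted p = 0.91), and the germ cell list 1 higher and 2 lower of 7 (2 and 2 over the list alone; adjusted p = 0.99), where Taf7l fell by 2.18. The endothelial list had 2 higher and 2 lower of 13 (4 and 3 over the list alone; adjusted p = 0.85), and Flt1, a VEGF receptor gene, fell by 1.56. For germ cell and endothelial genes the median, 0.15 and 0.24, and the mean, -0.20 and -0.028, differed in sign, and camera's direction was lower for the former and higher for the latter. Epithelial junction genes had 1 higher and 3 lower of 14 (1 and 3 over the list alone; adjusted p = 0.95), with a median of 0.11 a mean of -0.024 and a lower direction in camera. Of these, Esrp1, an epithelial splicing regulator, was at least 4.32-fold lower, while Cldn4 rose by 0.81, a call lost without control replicate 2 (adjusted p = 0.057).

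Among signalling, stress and housekeeping lists, calls went in both directions in some and in 1 direction in others. The FGF and ERK list had 6 higher and 3 lower of 14 (8 and 4 adjusted over the list alone; adjusted p = 0.088), with Etv4 and Dusp6, both transcribed downstream of FGF, higher by 1.01 and 1.13. Fgfr1 was at least 2.27-fold higher, while Fgfr2 fell by 0.96. The other called falls of this list, named after their values were seen, were Egr1, by 1.53, and Phlda1, by 0.76. The Wnt target list had 4 higher and 1 lower of 8 (5 and 2 over the list alone; adjusted p = 0.15), with Cdx1 higher by 0.88 while the Wnt inhibitor gene Dkk1 fell by 1.57. The Sox family list, from which the targets were left out, had 3 higher and 2 lower of 10 (4 and 2 over the list alone; adjusted p = 0.15). Sox9 rose by 1.42, from 248 to 692 intensity units, and Sox10 was at least 1.99-fold higher. Sox21 fell by 1.12 (adjusted p = 0.0070), and its second probe fell by 0.67; the call of the gene was lost without control replicate 2 (adjusted p = 0.057). The hypoxia list had 6 higher and 1 lower of 20 (7 and 1 over the list alone; adjusted p = 0.11), where the peptide hormone gene Adm rose from 35.8 to 130.2 intensity units. Ndrg1 fell by 0.86, a call lost without control replicate 1 or control replicate 2 (adjusted p up to 0.076). The p53 list had 3 higher and 0 lower of 16 (3 and 0 over the list alone; adjusted p = 0.20), with Plk3 higher by 1.16. The interferon list had 3 higher and 1 lower of 11 (3 and 1 over the list alone; adjusted p = 0.72), and the RNA sensor gene Ddx58 fell by 1.34. Ifitm3 and Bst2 rose by 0.77 and 0.81, and Ifit2 was at least 1.49-fold higher. Their calls were lost without control replicate 2 for Ifitm3 (adjusted p = 0.073), without control replicate 1, control replicate 2 or knockdown replicate 3 for Bst2 (adjusted p up to 0.11) and without any single array for Ifit2 (adjusted p up to 0.12). Cholesterol synthesis had 1 of 17 genes lower (0 over the list alone; adjusted p = 0.72), Lss, which fell by 0.49 and lost its call without any single array (adjusted p up to 0.17). Among housekeeping genes 1 of 11 was higher (1 over the list alone; adjusted p = 0.72). Tbp rose by 0.48, a call also lost without any single array (adjusted p up to 0.11), and its other probe differed by -0.65 and was not called.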

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

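Under the alternatives run, Sox7 and Sox17 stayed lower and called, the other named genes kept their direction, and so did the 14 shifted lists. Camera's direction turned only for lists near 0 that passed in no such setting. These were primitive streak genes (median 7.9e-16, in effect 0, with no filter, 0.097 at the 0.01 noise level on 2 arrays, 0.050 with the block, 0.045 to 0.18 with 1 array left out) and epithelial genes (0.12 at the 0.01 noise level on all 5 arrays, 0.062 with the block, -0.060 to 0.17 with 1 array left out). The others were germ cell genes (0.15 with the floor, 0.14 with the block, 0.11 to 0.20 with 1 array left out) and cholesterol synthesis (0.016 to 0.15 with 1 array left out). The 2 filters at the 0.01 noise level were chosen after seeing the data. The number of changed probes and genes, 2165 and 1643, did depend on the settings. It was 3404 and 2604 with intensities shifted by the array minimum plus 50, and 3416 and 2627 with trend and robust variance. With no filter it was 979 and 770. There 24613 probes share the adjustment, and the dim probes also enter the variance estimate shared between probes. Sox17 kept its difference of -2.60 there, with a limma adjusted p of 0.017, and these effects were not separated. At an adjusted p below 0.01 the numbers were 678 and 526, and at 1.5-fold or more 1090 genes remained. Leaving out 1 array gave 594 to 1460 probes and 443 to 1108 genes, the lowest without control replicate 2, with 1 control array left whose spread is assumed to be that of the knockdown arrays. The labels name no pairing by replicate number, only 2 numbers are shared, and same-numbered deviations correlated at 0.0072 and 0.073. The deviations of the 2 control arrays mirror each other, so these are not separate checks. A pairing is therefore not excluded. A fit with the replicate number as a block, in which knockdown replicate 3 adds nothing to the difference, called 1090 probes and 828 genes and left 14 lists shifted. Of the 14 lists shifted by camera at its preset correlation, 0 passed with an estimated correlation, where the lowest adjusted p was 0.11, while fry called 21 lists. The estimate was under the preset 0.01 for some of these lists, such as primitive endoderm regulators (-0.0026) and collagen folding (-0.017). For others it was higher, up to 0.195 for basement membrane genes. This alternative cannot separate an effect of correlation from that of the few residual degrees of freedom. In the other alternatives 14 to 17 lists were shifted and the 14 were always among them. Those alternatives kept the preset correlation, so they do not test the reliance on the spread between genes. Over 120 other named genes and all alternatives, 1321 of 1531 values kept their side of the threshold, 198 lost the call and 12 gained it. Of 110 named genes called, 72 stayed called with each array left out. Of 289 called genes with several tested probes, 173 had another probe that was not called, and for 1, Creb3, another probe was called in the opposite direction. Except where the threshold was stricter, the cause of these differences was not tested. Background correction of the unused signals was not run, nor was median scaling, since the table already has 1 distribution, and filters on detection p-values were replaced by the noise levels. Probes near the noise threshold limit what can be seen: 10989 probes were not tested.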

Other observations

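The scan of symbol families, the counts by Hox cluster and the tests of the explanations below were chosen after the results were seen, while the values of single genes and of the interferon list come from the planned fit and lists. Grouping the tested genes by the letters at the start of their symbols gave 317 families of at least 5 genes, of which 2 passed camera after Benjamini-Hochberg adjustment. The Hoxb genes, which lie side by side on 1 chromosome, were higher, with 6 of 8 called and a median of 1.34 (adjusted p = 6.5e-05, but adjusted p = 0.99 with an estimated correlation). Hoxb5, Hoxb1, Hoxb2, Hoxb6, Hoxb9 and Hoxb7 rose by 1.88, 1.69, 1.62, 1.36, 1.31 and 1.05, and Hoxb4 and Hoxb13 were not called. In the Hoxa cluster 2 of 5 rose and 0 fell, with a median of 1.29, and no difference between clusters was tested. In the Hoxc cluster Hoxc6 rose by 1.54 while Hoxc13 fell by 1.42, and in the Hoxd cluster Hoxd8 fell by 1.48, Hoxd9 fell by 1.45 and Hoxd4 rose by 0.56. The call of Hoxd4 was lost without any single array (adjusted p from 0.051 to 0.15) and that of Hoxc13 without any but knockdown replicate 1 (0.055 to 0.16). The sorting nexins, which act in endosomal sorting, were lower, with 7 of 21 called, 0 higher and a median of -0.34 (adjusted p = 0.0061, but adjusted p = 0.99 with an estimated correlation). Snx7 fell by 0.88 and Snx9 fell by 0.87, the latter not called without control replicate 2 (adjusted p = 0.057). Ribosomal proteins served as a contrast, with a median of -0.039 over 49 genes, 1 higher and 2 lower.

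The probe for Psmc1 went from noise in control cells to 1248 intensity units, the largest difference measured here. A rise of the whole proteasome is argued against, because the other 34 tested subunits had a median difference of 0.199 and a highest value of 0.54, with 3 called higher. A gain of the genomic region that takes in the neighbouring genes is argued against as well. The 3 nearest tested genes on each side had a median difference of 0.0197. The next tested gene on one side, Kcnk13, fell by 2.81 and is among the 12 largest falls. A change confined to Psmc1, or a local one that reaches only part of these neighbours, was not tested and stays open. That a proteasome subunit used by every cell was not seen in control cells suggests that the probe reports something other than the usual transcript, such as a variant or foreign RNA, which was not tested. An effect of the knockdown on this gene itself also stays open.

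The endoderm lists fell together: of 47 distinct tested genes of the 3 lists, 36 fell and 1 rose. A lower share of endoderm cells alone was predicted to raise the genes of other cell states alike. The 8 lists of other cell states differed from each other (permutation p = 0.022 over 100000 permutations of 88 genes), with medians from -0.21 for trophoblast to 0.75 for fibroblast genes. However, a smaller share would raise only genes of the cells that remain, and which states these hold is not known. The comparison of the 8 lists was the second made for that explanation. It followed one of Hox with pluripotency genes that had been picked for its size, and genes are not independent. Unequal lists thus do not argue against a smaller share of endoderm cells, which stays open. A shift towards 1 other state and a direct effect of the transcription factors stay open, as does an interferon response to introduced RNA. The interferon list had a median of 0.0722 with 3 members higher and 1 lower, which decides nothing. Fry called it higher (adjusted p = 0.0018), but fry called 21 of the 28 lists. Irf7, Irf9 and Stat2 were not called. Ifit1, Ifit3, Oasl1, Oasl2, Rsad2, Mx1, Mx2, Ifih1 and Cxcl10 had probes that did not pass the filter. Whether those probes can detect their transcripts is not known. A gain or loss of whole chromosomes in the knockdown cells is argued against by the chromosome medians, which over 20 chromosomes lay between -0.054 and 0.0601 (smallest camera adjusted p = 0.94).

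Of 9 tested fibroblast markers 6 rose, and 4 were called without knockdown replicate 2 or without knockdown replicate 3. Fibroblasts in the knockdown cultures are a candidate explanation. Fibroblasts bring abundant fibrillar collagen transcripts, and the highest median knockdown intensity of the probes of Col1a1, Col1a2 and Col3a1 was 13.4, under the noise threshold of 20.1. This excludes nothing, since no array shows that these probes can detect their transcripts, and the Col1a1 probe read 13.4, 24.8 and 7.30 in knockdown against 1.76 and -7.37 in control arrays. Of the 9 tested fibroblast markers, Twist2 was also on the mesenchymal list. Col5a1, Col6a1 and Dpt differed by -0.084, 0.38 and 0.12 and were not called. Col5a2, Lum, Postn, Prrx1 and S100a4 had probes as well, but these did not pass the filter. Fibroblasts and a mesenchymal expression state of the F9 cells themselves cannot be told apart here. The probes of Col1a1, Col1a2 and Col3a1 lie at the noise level, and of the tested markers 6 rose and 3 were not called.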
